A study of Mus musculus with 7 samples.

How the data were processed

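Libraries from whole abdominal aorta were compared between 2 groups, 3 labelled ITA-LNP and 4 labelled control-LNP. The groups and replicate numbers were taken from the sample titles, which write NP where the treatment protocol writes LNP; both were taken to mean the same particles. Per the labels' protocols, total RNA was extracted with TRIzol and a column kit, and 500 ng of it went into QuantSeq 3′ mRNA libraries, in which reads come from the 3′ end of transcripts and gene length does not enter the level. The genome build is mm10, per the submitters' processing notes. The aligner, the read counter, the annotation and the handling of molecular identifiers and strand are not given in the sources used here.

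The values deposited by the authors are on a log10 scale, in 1 table of 32544 genes and 7 libraries. Their base and pseudocount were worked out from the values. Raising 10 to each value and subtracting 1 gave columns that each sum to 1000000, so the values were read as log10 of CPM + 1, CPM being reads per 1000000 reads assigned to the listed genes. Within each library the CPM were whole multiples of 1 step, and 100% of the values came out as whole reads within a tolerance of 0.01. This gave the depth of each library, from 5077073 to 7281721 reads, largest over smallest 1.43. A gene at 0 reads was given an upper limit of 3 reads, or 0.412 to 0.591 CPM. These limits cover counting error only, since PCR copies were not told apart from separate molecules. Of the 32544 genes, 14938 were at 0 in all 7 libraries, and 31400 names matched GENCODE M21, which gave coordinates on mm10. Ctgf and Cyr61 were matched through their newer symbols Ccn2 and Ccn1. G6b had no match and is given without coordinates.

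The design written before the data were examined assumed deposited log2 CPM. Because the values are log10 of CPM + 1, they were converted to log2(CPM + 1), a pseudocount of 1 CPM, and the filter for low values became a mean log2(CPM + 1) of at least 1 over all libraries. This kept 12636 genes. Fold changes on this scale understate the change of low genes. The main test was limma-trend (limma 3.58.1 in R 4.3.3) with ITA-LNP against control-LNP in all 7 libraries and no covariate, and with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A positive log2 fold change means higher with ITA-LNP, and errors after ± are standard errors of the fold change unless SD is written. Tested on simulated counts of 13590 genes with the same library sizes and 200 changed genes, at a dispersion of 0.318, the median over genes in the ITA-LNP libraries, the procedure recovered 22% of 4-fold and 98% of 16-fold changes and called 7 unchanged genes. In control-LNP replicates 1, 3 and 4 that dispersion was 0.0634, at which recovery was not simulated. Nor was recovery simulated with a library as far from its group as control-LNP replicate 2. The measured libraries gave 1957 changed genes with that replicate and 3964 without it. The shares recovered therefore hold for the simulated counts only and do not describe the comparison of all 7 libraries.

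Fixed before the data were examined were 39 gene lists with 637 entries, of which 634 were in the table, covering pathways, wall cell types, blood cells and neighbouring tissues. The 34 lists with at least 4 tested genes were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes. Camera with a correlation estimated per list, camera on ranks and fry were alternatives. The mean log2(CPM + 1) of a list's tested members in each library, its list score, was compared by an exact two-sided permutation test over all 35 splits, whose smallest p is 0.0286. A platelet and a natural killer cell list were added after the values were seen and are given as a description.

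Genes were named by a rule fixed before the data were examined. It named Abca1, Abcg1, Nr1h3, Acod1 and Apoe in any case. It then named the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted and clone names. Of each described list it named the first members by p, 2 to 4 of them, or up to 6 where the list passed camera. Any other gene is said to have been chosen after its values were seen. Some genes that the rule names are not reported here; they stayed in the tests and in the counts of the lists.

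The alternatives were no filter, a mean of at least 2, median centring, quantile normalization, a variance prior without the trend, a robust prior, sample weights, a replicate block, the white adipocyte score as a covariate, an adjusted p under 0.1, and leaving out each library in turn. Pseudocounts of 0.25 and 4 CPM, limma-voom on the recovered reads and median centring without control-LNP replicate 2 were added after the data were seen, and voom called 1768 genes. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. No value column was left out.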

Results

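RNA was measured in whole abdominal aortas of male Apoe-/- mice, which lack apolipoprotein E and develop atherosclerotic plaques, after 12 weeks on a high-fat diet. The mice received 50 mg/kg of ITA-LNP or of a control LNP into the vein 1 time a week. LNP is the usual abbreviation of lipid nanoparticle, and ITA is taken from the series title to stand for itaconate, a metabolite that macrophages make from the TCA cycle. There were 3 ITA-LNP and 4 control-LNP libraries, made by 3′ mRNA sequencing. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries, part of which may be technical. The ITA-LNP libraries held 6375381, 6785983 and 7281721 reads and the control-LNP libraries 5077073, 6688872, 5199357 and 6097749 reads. A gene at 0 reads could lie at up to 0.412 to 0.591 CPM (reads per 1000000 reads), depending on the library. Such limits cover counting error only.

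The series title asks whether itaconate lowers the cholesterol burden through the exporter ABCA1 and cholesterol efflux, and the design compares ITA-LNP with control-LNP aortas. The ITA-LNP libraries were rich in transcripts of the vessel wall, and the libraries labelled control-LNP were rich in transcripts of blood cells. The structural extracellular matrix genes summed to 34869 ± 1955 CPM in the ITA-LNP libraries and 254 ± 76.8 CPM in the control-LNP libraries (SD, n = 3 and 4), a ratio of 137. In the opposite direction, the summed B and plasma cell markers were 18.8 times and the neutrophil markers 137 times as high in the control-LNP as in the ITA-LNP libraries, the latter 58.2 times without control-LNP replicate 2. Of 12636 genes tested, 1957 changed, of which 1306 were higher and 651 lower with ITA-LNP. The change exceeded 16-fold for 811 of the higher and 253 of the lower genes. Control-LNP replicate 2 stood apart: 10846 genes were detected in it, against 14232 to 15333 in the other control-LNP and 12226 to 12856 in the ITA-LNP libraries. Its correlation with the other control-LNP libraries across genes was 0.607 to 0.625, while those correlated with each other at 0.933 to 0.949. The ITA-LNP libraries correlated with each other at 0.7108 to 0.7375.

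**Figure D1:**
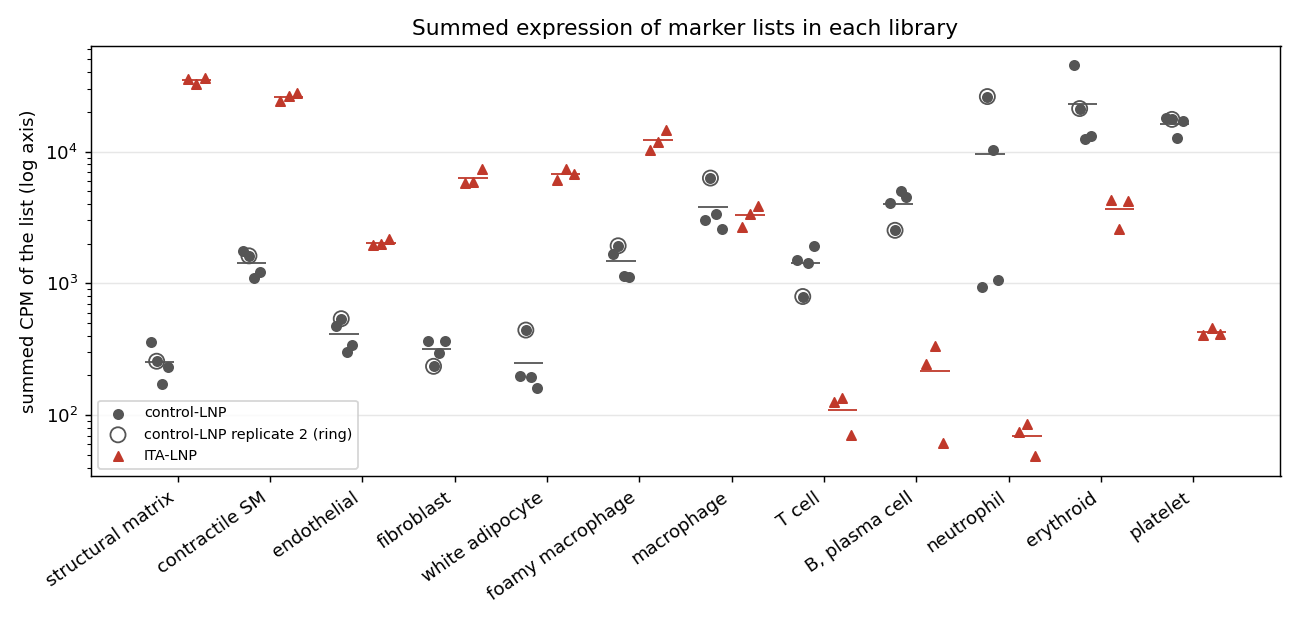
Summed CPM (log axis) of marker lists in each library, with 1 point per library, a line at the group mean and a ring around control-LNP replicate 2. The matrix list lies between 32622 and 36173 CPM in the 3 ITA-LNP libraries and between 173 and 357 CPM in the 4 control-LNP libraries, and the platelet list, which was added after the values were seen, lies on the opposite side.

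The 12 genes with the largest rises had log2 fold changes of 7.56 to 7.88. They were Ctgf, Cyr61, Spp1, Igfbp7, Myh11, Fblim1, Mt1, Col2a1, Mt2, Ibsp, Prelp and Cspg4. Ctgf (chromosome 10, 24595442 to 24598683) and Cyr61 (chromosome 3, 145646976 to 145649981), which encode secreted proteins that bind the matrix, reached 956 against 3.15 CPM and 661 against 1.96 CPM in ITA-LNP and control-LNP libraries. For Ctgf the log2 fold change was 7.88 ± 0.57 (SE; adjusted p = 5.02e-05, limma). Spp1 (chromosome 5, 104435118 to 104441050), which encodes osteopontin, was at 3717 against 17.2 CPM (7.74 ± 0.42, adjusted p = 9.3e-06). Myh11 (chromosome 16, 14194535 to 14291372), the smooth muscle myosin heavy chain, was at 1561 against 7.02 CPM (7.68 ± 0.50, adjusted p = 2.26e-05). Mt1 and Mt2 encode metallothioneins and are close paralogs, so the counting could split reads between them. Each of the 12 genes kept its call when any 1 library was left out. Reads carried over from the ITA-LNP libraries may be a source of such low control-LNP levels, as described below. They would limit these folds and could set the ranking.

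The 12 genes with the largest falls had log2 fold changes of -7.97 to -7.08 and were Ccl5, P2ry12, Gp9, Gzma, Ighd, Nrgn, G6b, Btla, Pax5, Bank1, Hcst and Coro1a. Ccl5 (chromosome 11, 83525778 to 83530518), a chemokine of T cells and platelets, was at 4.53 against 1425 CPM (-7.97 ± 0.48, adjusted p = 1.45e-05). P2ry12 (chromosome 3, 59216272 to 59262871), the ADP receptor of platelets, was at 1.11 against 352 CPM, and Gp9 (chromosome 6, 87778072 to 87779768), a subunit of the platelet receptor for von Willebrand factor, at 0.693 against 282 CPM. Nrgn (chromosome 9, 37544492 to 37552904), a calmodulin-binding protein that platelets also carry, was the most abundant of them at 45.9 against 7140.3 CPM (-7.25 ± 0.30, adjusted p = 2.65e-06). Pax5 (chromosome 4, 44524757 to 44710487), the transcription factor of B cell identity, was at 0.668 against 227 CPM, with an ITA-LNP mean of 0.412 CPM without ITA-LNP replicate 2. These 12 genes, too, kept their calls when any 1 library was left out. Whether reads carried over from the control-LNP libraries set the low ITA-LNP levels, and so the size of these falls, was not tested.

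Smooth muscle and matrix genes rose together. All 21 tested structural extracellular matrix genes were higher (21 higher when adjusted over the list alone; camera adjusted p = 1.47e-25; adjusted p = 0.0648 with an estimated correlation), led by Col3a1 (7.11 ± 0.32, adjusted p = 5.67e-06) and Col1a2 (7.35 ± 0.36, adjusted p = 5.84e-06). Of the contractile smooth muscle genes, 18 of 19 were higher (19 higher when adjusted over the list alone; camera adjusted p = 2.17e-17; adjusted p = 0.0648 with an estimated correlation). Acta2, the smooth muscle actin, was at 10802 against 98.9 CPM (6.79 ± 0.27, adjusted p = 2.65e-06), and Tagln, an actin-binding protein, at 3503 against 21.6 CPM. The member that did not pass, Pln, is named after its values were seen and had a log2 fold change of 2.65 ± 0.93 (adjusted p = 0.0930; 0.0141 without ITA-LNP replicate 1). Among the modulated smooth muscle and cartilage genes, 13 of 17 were higher (14 higher when adjusted over the list alone; camera adjusted p = 6.27e-11; adjusted p = 0.0648 with an estimated correlation), including Mgp (7.48 ± 0.42, adjusted p = 1.03e-05), an inhibitor of calcification. Of 19 matrix proteases and inhibitors, 13 were higher and 2 lower (14 higher and 2 lower when adjusted over the list alone; camera adjusted p = 1.42e-08; adjusted p = 0.0648 with an estimated correlation). Ctsl, a lysosomal protease, and Adamts1 were higher, with log2 fold changes of 6.98 ± 0.37 and 7.39 ± 0.60, and Timp3, whose last exon overlaps an exon of Syn3 on the other strand, rose by 6.25 ± 0.63. The 2 lower members, named after their values were seen, were the neutrophil proteases Mmp8 (adjusted p = 0.0168) and Mmp9 (adjusted p = 0.0148). In the control-LNP libraries the structural matrix genes stood at a median of 0.386% to 0.907% of their ITA-LNP level. Mmp8 lost its call without ITA-LNP replicate 1, 2 or 3 or control-LNP replicate 3 (adjusted p up to 0.0643), and Mmp9 without ITA-LNP replicate 2 or 3 or control-LNP replicate 3 (up to 0.0632).

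Other wall and perivascular cell types moved the same way. Endothelial genes were higher in 10 of 15 (10 higher when adjusted over the list alone; camera adjusted p = 4.07e-06; adjusted p = 0.0720 with an estimated correlation), among them Ptprb (6.93 ± 0.66, adjusted p = 0.000196) and Egfl7 (7.18 ± 0.75, adjusted p = 0.000305). Fibroblast genes were higher in 10 of 14 (11 higher when adjusted over the list alone; camera adjusted p = 6.23e-09; adjusted p = 0.0648 with an estimated correlation), led by the small proteoglycans Dcn (3887 against 37.4 CPM) and Lum (652 against 3.87 CPM). White adipocyte markers summed to 6767 ± 642 against 249 ± 129.8 CPM. Of 10 tested, 4 were higher (8 higher when adjusted over the list alone; camera adjusted p = 0.000903; adjusted p = 0.134 with an estimated correlation), with the fatty acid carrier Fabp4 at 6271 against 128 CPM (6.06 ± 0.57, adjusted p = 0.000184) and the lipid droplet protein Plin4 at 138 against 0.335 CPM. Without control-LNP replicate 2 the control-LNP means of Fabp4 and Plin4 were 61.2 and 0.197 CPM. Of 10 Schwann cell and neuron markers, 4 were higher (7 higher when adjusted over the list alone; camera adjusted p = 0.00539; adjusted p = 0.149 with an estimated correlation), including Stmn2 (5.23 ± 0.87) and Dbh (4.47 ± 0.74), the enzyme that makes noradrenaline. That list lost its call when genes had to reach a mean log2(CPM + 1) of 2 (adjusted p = 0.356). Brown adipocyte markers, with 5 genes tested, did not pass camera (adjusted p = 0.151, 0.00354 with fry). The skeletal muscle, adrenal cortex, kidney, pancreas and mesothelial lists had under 4 tested genes. They summed to 12.9 ± 16.4 against 7.28 ± 6.77 CPM, 0.928 ± 1.38 against 11.3 ± 9.07 CPM, 5.33 ± 5.86 against 5.64 ± 4.82 CPM, 11.7 ± 14.0 against 25.4 ± 18.8 CPM and 19.7 ± 15.1 against 2.29 ± 2.20 CPM, respectively, in ITA-LNP against control-LNP libraries. The ITA-LNP sums of the first 3 were 3.50, 0.137 and 2.04 CPM without ITA-LNP replicate 1, and that of the pancreas list 3.92 CPM without ITA-LNP replicate 2. Without control-LNP replicate 1 the control-LNP sums of the skeletal muscle and mesothelial lists were 4.25 and 1.21 CPM.

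Blood cell markers were lower with ITA-LNP. Of 15 B and plasma cell markers, 11 were lower (14 lower when adjusted over the list alone; camera adjusted p = 2.06e-11; adjusted p = 0.0801 with an estimated correlation), with Cd79a (-6.47 ± 0.63, adjusted p = 0.000224), a chain of the B cell receptor. Of 16 T cell markers, 9 were lower (13 lower when adjusted over the list alone; camera adjusted p = 3.78e-09; adjusted p = 0.140 with an estimated correlation), with Lck (-5.86 ± 0.77, adjusted p = 0.000992) and Il7r (-3.62 ± 0.48, adjusted p = 0.00101). The MHC class II list had 5 of 9 lower members (8 lower when adjusted over the list alone; camera adjusted p = 8.51e-07; adjusted p = 0.140 with an estimated correlation), with H2-Ab1 (-3.62 ± 0.36, adjusted p = 0.000245) and H2-Ob (-5.78 ± 0.75, adjusted p = 0.000923). The neutrophil markers summed to 69.8 ± 19.2 against 9585 ± 11862 CPM, and the control-LNP values ranged from 939 to 26143 CPM, the highest being replicate 2, without which their mean was 4066 CPM. Of 7 neutrophil genes tested, 4 were lower (6 lower when adjusted over the list alone; camera adjusted p = 5.25e-05; adjusted p = 0.245 with an estimated correlation), with the calcium-binding alarmins S100a9 (-6.43 ± 1.01, adjusted p = 0.00234) and S100a8 (-5.97 ± 1.19, adjusted p = 0.00760). With voom both lost their calls at larger folds, of -6.61 and -6.17 (adjusted p = 0.497 and 0.525), as did Retnlg (-6.79 in place of -6.23, adjusted p = 0.413). Globin genes led the erythroid list, where 5 of 9 were lower (5 lower when adjusted over the list alone; camera adjusted p = 9.04e-05; adjusted p = 0.245 with an estimated correlation). Hba-a2 and Hba-a1, near-identical copies between which the counting could split reads, had log2 fold changes of -2.29 ± 0.33 and -2.46 ± 0.37. A platelet list and a natural killer cell list were added after the values were seen and hold genes already known to be among the largest falls, so their counts are a description and no test. Of 20 platelet markers, 18 were lower and 1, Selp, higher, and the sum was 424 ± 26.4 against 16323 ± 2419 CPM. Of 14 natural killer genes 8 were lower. Selp, which endothelium also makes and which is named after its values were seen, lost its call without ITA-LNP replicate 1, 2 or 3 (adjusted p up to 0.106).

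Macrophage genes went both ways. Of 18 macrophage markers, 6 were higher and 4 lower (6 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.632, 0.0359 with fry), with the complement chain C1qb at 62.0 against 2.27 CPM (4.64 ± 0.94, adjusted p = 0.00800; control-LNP mean 0.862 CPM without control-LNP replicate 1) and the Fc receptor chain Fcer1g at 78.2 against 476 CPM (-2.59 ± 0.54, adjusted p = 0.00953). Of 17 foamy macrophage genes, which lipid-laden macrophages express and of which other wall cells express several, 11 were higher and 1 lower (13 higher and 1 lower when adjusted over the list alone; camera adjusted p = 3.4e-07; adjusted p = 0.0853 with an estimated correlation). Spp1, named above, was followed by Gpnmb (6.68 ± 0.57, adjusted p = 0.000107), Ctsb (2.64 ± 0.27, adjusted p = 0.000277) and Lpl (5.97 ± 0.69, adjusted p = 0.000513), the lipoprotein lipase. The lower member, Cd9, was named after its value was seen (-1.23 ± 0.33, adjusted p = 0.0328) and lost its call without ITA-LNP replicate 1, 2 or 3 or control-LNP replicate 1 or 4 (adjusted p up to 0.110). Of 13 efferocytosis genes, which serve the uptake of dead cells, 8 were higher (9 higher when adjusted over the list alone; camera adjusted p = 0.000113; adjusted p = 0.149 with an estimated correlation), led by the bridging proteins Mfge8 (7.17 ± 0.64) and Gas6 (6.79 ± 0.74). Beside these lists, the summed T cell markers were 12.8 times and the platelet markers 38.5 times as high in the control-LNP as in the ITA-LNP libraries. The summed matrix genes were 137 times as high in the ITA-LNP libraries. Whether macrophages or wall cells were the source of the efferocytosis transcripts was not tested.

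Abca1 (chromosome 4, 53030787 to 53159895), which exports cholesterol from cells, was measured at 163, 236 and 327 CPM with ITA-LNP and at 112, 1.35, 71.0 and 69.0 CPM in control-LNP replicates 1 to 4. All ITA-LNP values lay above all control-LNP values, but the log2 fold change of 2.78 ± 1.20 did not pass (adjusted p = 0.158). Without control-LNP replicate 2 it was 1.50 and passed (adjusted p = 0.0106), as it did with the remaining libraries centred on their medians (1.27, 0.0173). With all libraries it passed with quantile normalization (1.91, 0.0264) and with sample weights (1.60, 0.0211). Over the other settings its adjusted p was 0.0765 to 0.663. Abcg1 (chromosome 17, 31057675 to 31117988), a further sterol exporter, had a log2 fold change of 0.83 ± 1.02 (adjusted p = 0.659), which was -0.12 without control-LNP replicate 2. Nr1h3 (chromosome 2, 91184061 to 91202834), which encodes the sterol-sensing receptor LXRα, was at 13.2 against 1.76 CPM (2.33 ± 0.93, adjusted p = 0.132), on 271 and 39 reads, with an ITA-LNP mean of 7.40 CPM without ITA-LNP replicate 2. The 95% intervals of the log2 fold changes of Abcg1 and Nr1h3 were -1.47 to 3.13 and 0.23 to 4.43, and that of Abcg1 allowed changes of several-fold either way. Acod1 (chromosome 14, 103046977 to 103056573), whose enzyme makes itaconate, was below the filter, with 6, 0 and 0 reads in the ITA-LNP and 17, 1, 3 and 0 reads in the control-LNP libraries. Between the same libraries the summed matrix genes differed by 137 times and the summed B and plasma cell markers by 18.8 times in the opposite direction.

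**Figure D2:**
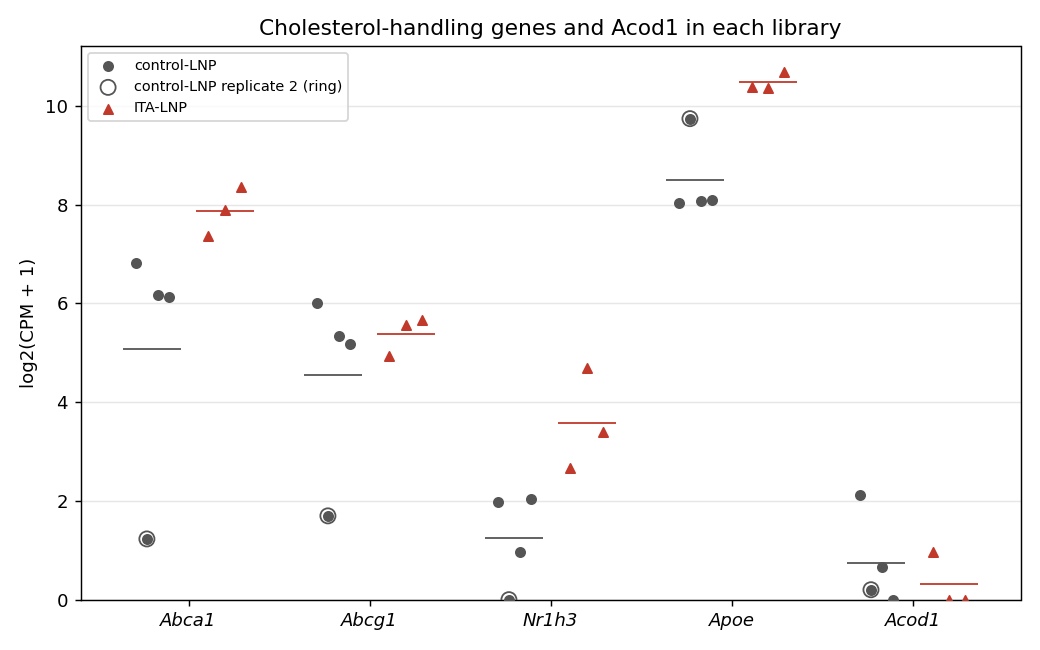
log2(CPM + 1) of 4 cholesterol-handling genes and Acod1 in each library, with 1 point per library, a line at the group mean and a ring around control-LNP replicate 2. Abca1 lies at 7.36 to 8.36 in the ITA-LNP libraries, at 6.13 to 6.82 in control-LNP replicates 1, 3 and 4, and at 1.23 in control-LNP replicate 2.

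As a list, the cholesterol efflux and LXR targets did not pass (camera adjusted p = 0.618), and 1 of 16 was higher (0 when adjusted over the list alone). This was Ch25h, the enzyme that makes 25-hydroxycholesterol, at 16.2, 1.33 and 42.0 CPM with ITA-LNP and 0 reads in all control-LNP libraries, at least 33.6-fold higher as a mean against the limit per library, or 14.8-fold without ITA-LNP replicate 3. Its call (adjusted p = 0.0387) was lost without ITA-LNP replicate 1 or 3 or control-LNP replicate 1, 3 or 4 (adjusted p up to 0.116). Abca7, another lipid transporter and second by p in the list, had a log2 fold change of -3.60 ± 1.24 (adjusted p = 0.0873; 0.00105 without control-LNP replicate 2). Of 22 genes for cholesterol synthesis and uptake, the squalene synthase gene Fdft1 was higher and 1 gene was lower (camera adjusted p = 0.304). Adjusted over the list alone, 0 were higher and 1 was lower. Fdft1 (2.99 ± 0.85, adjusted p = 0.0416) lost its call without ITA-LNP replicate 1, 2 or 3 or control-LNP replicate 3 or 4 (adjusted p up to 0.156). Apoe (chromosome 7, 19696109 to 19699188) was at 1433 against 416 CPM (1.99 ± 0.42, adjusted p = 0.00969), with a control-LNP mean of 269 CPM without control-LNP replicate 2. It lost its call without ITA-LNP replicate 3 (adjusted p = 0.0536), with median centring (0.86, 0.674; 2.17, 0.000176 without control-LNP replicate 2) and with a variance prior that ignores the trend (0.0860). A 3′ tag outside the part deleted in the knockout does not check the genotype. The differences in matrix and B cell markers stand beside these genes too.

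Inflammatory genes went both ways. Of 20 cytokine and adhesion genes, 6 were higher and 2 lower (7 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.199, 0.00233 with fry and 0.0474 without control-LNP replicate 2). The adhesion receptor Vcam1 was at 1339 against 15.4 CPM (6.46 ± 0.48, adjusted p = 6.03e-05) and Ccl5, named above, was lower. Of genes chosen after their values were seen, the neutrophil chemokine Cxcl1 (111 against 0.538 CPM) and the monocyte chemokine Ccl2 (35.9 against 0.345 CPM) were higher, and Il1b (2.93 against 657 CPM) was lower (-5.89 ± 1.22, adjusted p = 0.00913; -6.52 and 0.313 with voom). The control-LNP mean of Il1b was 118 CPM without control-LNP replicate 2 and its ITA-LNP mean 1.64 CPM without ITA-LNP replicate 1, and the ITA-LNP mean of Cxcl1 was 69.6 CPM without ITA-LNP replicate 3. Of 21 interferon-stimulated genes, 1 was lower (0 when adjusted over the list alone), and the list passed as lower (camera adjusted p = 0.00552; adjusted p = 0.260 with an estimated correlation, 0.121 with fry). That gene was the transcription factor Irf1 (-2.65 ± 0.79, adjusted p = 0.0499), which lost its call without ITA-LNP replicate 2 or 3 or control-LNP replicate 1, 3 or 4 (adjusted p up to 0.170). Rtp4 came next (-3.02 ± 0.90, adjusted p = 0.0502; 0.0118 without ITA-LNP replicate 2, 0.0365 with median centring without control-LNP replicate 2). Of 18 targets of NRF2, a transcription factor of the oxidant response, 2 were higher (4 higher when adjusted over the list alone; camera adjusted p = 0.305, 0.00439 with fry and 0.0434 without control-LNP replicate 2). These were Cbr3 (4.63 ± 0.78, adjusted p = 0.00327), a carbonyl reductase, and Prdx1 (1.53 ± 0.37, adjusted p = 0.0211), a peroxidase, which lost its call without ITA-LNP replicate 2 or 3 (adjusted p up to 0.104). The summed neutrophil markers and T cell markers were 137 times (58.2 without control-LNP replicate 2) and 12.8 times as high in the control-LNP libraries beside these genes.

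Mitochondrial transcripts took at least 8.45% of the reads in each ITA-LNP library and at most 5.22% in each control-LNP library. Of 12 mitochondrially encoded genes, 7 were higher (8 higher when adjusted over the list alone; camera adjusted p = 7.35e-05; adjusted p = 0.149 with an estimated correlation), led by mt-Nd3 (2.07 ± 0.30) and mt-Co2 (1.72 ± 0.25). The list did not pass with median centring (adjusted p = 0.215, or 2.37e-05 without control-LNP replicate 2), where its direction held. Of 25 ribosomal protein genes, 16 were lower (17 lower when adjusted over the list alone; camera adjusted p = 1.83e-10; adjusted p = 0.168 with an estimated correlation), with Rpl23 (-1.52 ± 0.20, adjusted p = 0.000952) and Rps14 (-1.93 ± 0.31, adjusted p = 0.00283), though pseudogenes could share their reads. Both genes were also lower with median centring, without passing (adjusted p = 0.131 and 0.0881), and with quantile normalization, where they passed. mt-Nd3 and mt-Co2 did not pass with median centring either (adjusted p = 0.589 and 0.734), and all 4 genes passed with it without control-LNP replicate 2 (adjusted p up to 0.0148). With a variance prior that ignores the trend Rpl23 (0.106), Rps14 (0.0681), mt-Nd3 (0.0531) and mt-Co2 (0.0919) lost their calls. Of the 16 ribosomal calls 7, and of the 7 mitochondrial calls 5, were kept whichever library was left out. Of 19 immediate early and heat shock genes, 7 were higher (9 higher when adjusted over the list alone; camera adjusted p = 9.99e-06; adjusted p = 0.134 with an estimated correlation), led by Egr1 (1007 against 13.5 CPM) and the small heat shock protein Hspb1 (464 against 1.83 CPM). Of 14 clock genes 4 were higher (4 higher when adjusted over the list alone; camera adjusted p = 0.0791, 0.0294 without control-LNP replicate 2 and 0.0234 without ITA-LNP replicate 3), with Nr1d1 (5.47 ± 0.79) and Dbp (4.36 ± 0.95) first. With all libraries kept, the clock list passed without a filter (0.0240), with median centring (0.0251), with quantile normalization (0.0384) and with fry (0.0383). Beside these lists, the summed matrix genes were 137 times as high in the ITA-LNP libraries, and the T cell and platelet markers 12.8 and 38.5 times as high in the control-LNP libraries.

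The remaining lists did not pass camera in the design fixed at the start. Camera gave an adjusted p of 0.0791 for the lysosome list, 0.0791 for fatty acid oxidation and 0.0791 for the TCA cycle, with 3 of 19, 1 of 15 and 1 of 17 genes higher (3 higher when adjusted over the list alone, 1 higher and 1 higher when adjusted over the list alone). Without control-LNP replicate 2 these 3 lists passed as higher, at 0.0121, 0.0260 and 0.00698, and fatty acid oxidation also without ITA-LNP replicate 3 (0.0396). With all libraries kept, the lysosome, fatty acid oxidation and TCA cycle lists passed without a filter (0.0186, 0.0478 and 0.0186), with quantile normalization (0.0384, 0.0488 and 0.0441) and with camera on ranks (0.0414, 0.0277 and 0.0277). Fatty acid oxidation and the TCA cycle also passed with median centring (0.0251 and 0.0465), lysosome and TCA cycle with fry (0.0245 and 0.0279), and fatty acid oxidation with a replicate block (0.0372). The unfolded protein response had 3 of 16 higher (4 higher when adjusted over the list alone; 0.159) and fatty acid synthesis 3 of 15 (3 higher when adjusted over the list alone; 0.513). Glycolysis and hypoxia had 1 of 17 higher (1 higher when adjusted over the list alone; 0.977), and proliferation 0 of 16 in either direction (0.166). In the nuclear oxidative phosphorylation list, 1 of 22 was lower (0 when adjusted over the list alone; 0.834), and the camera direction was lower while the mean and median log2 fold changes were 0.23 and 0.17.

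**Figure D3:**
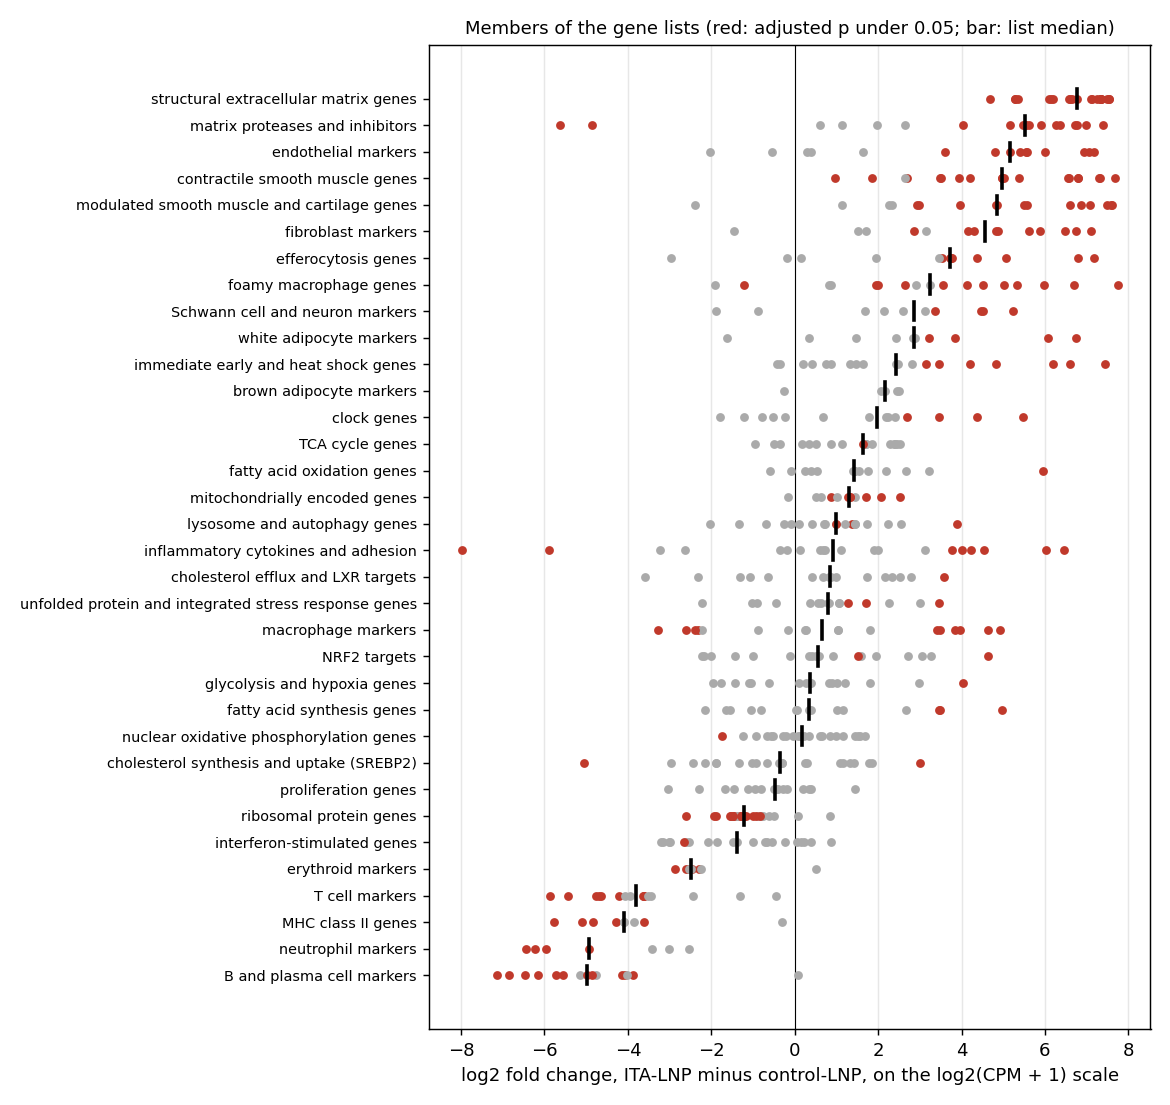
log2 fold change (ITA-LNP minus control-LNP, log2(CPM + 1) scale) of each tested member of the 34 tested lists, red where the adjusted p was under 0.05, with a bar at the list median. The matrix list has the highest median, 6.77, and the B and plasma cell list the lowest, -4.98.

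Of 34 lists tested, 19 passed camera, 12 as higher and 7 as lower, and 0 passed with an estimated correlation. Fry, a rotation test of whether a list's genes move on balance in 1 direction, called 25. In exact two-sided permutation tests of the list scores, 20 lists reached 0.0286, the smallest p that 35 splits allow, and these 20 passed after adjustment at 0.0486. The interferon, MHC class II, T cell and ribosomal lists passed camera but not this test (adjusted p = 0.0747), and the inflammatory, NRF2, brown adipocyte, TCA cycle and clock lists passed this test but not camera (camera adjusted p = 0.199, 0.305, 0.151, 0.0791 and 0.0791). The groups did not overlap for 1948 of the 1957 changed genes and for 29.9% of the 12636 tested, where chance gives 5.71%. Without control-LNP replicate 2, 3964 genes changed, 1982 in each direction, and 25 lists passed. Centring each library on its median put the median log2 fold change of all genes at -0.98, against 0.15 before, and gave 741 higher and 1249 lower genes, so 37.2% were higher in place of 66.7%. Quantile normalization put that median at -0.19 and gave 1614 higher and 1401 lower genes, or 53.5% higher. Centring moved every log2 fold change by -1.13, so rises shrank and falls grew, and this rested on control-LNP replicate 2: without it centring moved them by -0.23 and gave 1781 higher and 2447 lower genes (42.1% higher). With all libraries kept, centring also ended, among the genes named above, the calls of the rises of Ctsb (adjusted p = 0.355), Fabp4 (0.0593), C1qb (0.0540), Prdx1 (0.763), Ccl2 (0.0647), Ch25h (0.224) and Fdft1 (0.0682), whose folds were smaller. It also ended calls of falls whose folds were larger: Fcer1g (-3.72 in place of -2.59, adjusted p = 0.0930), Irf1 (-3.78 in place of -2.65, adjusted p = 0.109), Cd9 (-2.36 in place of -1.23, adjusted p = 0.188), Mmp8 (-6.76 in place of -5.63, adjusted p = 0.0523), Hba-a1 (-3.59 in place of -2.46, adjusted p = 0.0557) and Hba-a2 (-3.41 in place of -2.29, adjusted p = 0.0913). Each of these rises and falls passed with centring when control-LNP replicate 2 was left out (adjusted p up to 0.0411). The prior without the trend also ended those of Prdx1 (0.135), Cd9 (0.182), Fdft1 (0.0555) and Irf1 (0.0739), at the same folds. Voom ended the calls of Mmp8 (-7.21, 0.123), Mmp9 (-6.24, 0.0610), Fdft1 (3.21, 0.0545) and Irf1 (-2.87, 0.157), given as log2 fold change and adjusted p, at folds no smaller than those reported.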

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

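The tests of blood RNA, library size, treatment, few molecules, neutrophil share, carried-over reads, wall share and other splits of the libraries were chosen only after the results had been seen, as were the platelet and natural killer lists and the CPM ranges and bounds, which were set after looks at the data with other ranges. The test of the neutrophil share was put in place of a comparison of summed lists whose outcome was known. The search for control-LNP values far from the other 3 followed a fixed rule, and the ITA-LNP group, with 3 libraries, was not searched. The values searched included the added lists and genes chosen after their values were seen.

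In the first pattern, wall genes were higher and blood-cell genes lower in the ITA-LNP libraries. The tables argue against a difference in library size, since the largest total of reads was 1.43 times the smallest while the median structural matrix gene differed by 6.77 on the log2 scale. The summed CPM of 8 of 8 lists (matrix, contractile, endothelial, fibroblast, T, B, neutrophil and erythroid) lay, without overlap, on the side that RNA of blood cells in place of wall RNA in the libraries labelled control-LNP predicts, but this is the pattern itself and decides nothing. Such blood RNA and an action of the treatment on the same tissue cannot be parted by libraries with like shares of wall and blood. No library pair holds such shares, as the smallest ITA-LNP sum of the 4 wall lists was 22.6 times the largest control-LNP sum. The control-LNP levels argue against such an action as the whole cause. In these 4 libraries the matrix list summed to 173 to 357 CPM and the contractile list to 1096 to 1753 CPM. The erythroid list summed to 12434 to 45005 CPM in them. RNA mainly from aortic wall would hardly give such levels, but the series holds no reference library of wall or blood to check this. An action of the treatment beside the blood RNA cannot be told apart from it. Whether treatment changed the leukocytes held in the vessel is open and untested.

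In the second pattern, control-LNP replicate 2 stood apart from the other control-LNP libraries. Few distinct RNA molecules behind that library may be a source: of 61 genes at 8 to 64 CPM in the other 3, from 6 fixed lists of metabolic, lysosomal and stress genes, 13 (21.3%) had at most 1 read in it, against 0 of 61 to 65 genes in replicates 1, 3 and 4, chosen for each by its level in 2 libraries, without replicate 2. The tables argue against a larger share of neutrophils as the whole cause. The neutrophil list was 6.43 times its level in the other 3, and the T cell list was at 0.490 by summed CPM and 0.158 by list score, but dilution would lower a cell type's genes alike, while the upper over the lower quartile of the gene ratios was 126 for the T and 12.5 for the B cell list (at most 1.61 in replicates 1, 3 and 4). Other biological differences between the control-LNP aortas were not tested. Genes at 8 to 63 reads numbered 1586 to 2591 in the ITA-LNP libraries and 1367 in control-LNP replicate 2. In control-LNP replicates 1, 3 and 4 they numbered 4254 to 4710. Whether few distinct molecules lay behind the ITA-LNP libraries too, and set some of the falls, was not tested.

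In the third pattern, the control-LNP libraries held wall transcripts at low levels. In replicate 2, of 1861 genes at 0.5 to 4 CPM in the other 3 that were lower in the ITA-LNP libraries, 78.9% were at 0 reads, while of 243 genes of that level at 64 CPM or more in the ITA-LNP libraries 2.06% were (Fisher's exact test, p = 2.82e-132, across genes, which are not independent). This argues against a small share of wall tissue in that library, and reads carried over from the ITA-LNP libraries may be the source. In replicates 1, 3 and 4 the matrix genes stood at a median of 0.907%, 0.386% and 0.556% of their ITA-LNP level. Single matrix genes ranged from 0.338% to 2.24%, from 0.186% to 1.20% and from 0.234% to 2.73% in these 3 libraries. There a small share of wall tissue and carried-over reads cannot be told apart, since both predict about 1 ratio for the matrix genes. The source of the spread around the medians was not tested.

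Of the 35 splits into 3 and 4 libraries, 1, the real one, gave as many as 1957 changed, 1306 higher or 651 lower genes. That share, 1 in 35, is the smallest the splits allow. The test was also chosen after the results were seen, so it cannot exclude chance. The highest others were 829 changed, 720 higher and 109 lower genes, all with control-LNP replicates 1, 3 and 4 against the rest. Those 720 genes were higher in these 3 control-LNP libraries, so they were lower on the side that held the ITA-LNP libraries. Counted by side, that split passes the real 651 lower genes. That split differs from the real one in the place of control-LNP replicate 2 alone, so its calls were not parted from the group difference. For the gene lists, 12 of the 35 splits called 19 or more, with 22 as the highest other, so chance cannot be excluded for that count.

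Of 129 values searched, 19 had a control-LNP library far from the other 3, where chance gives about 1 in 20. The values come from the same libraries and are not independent, so these are not 19 separate observations. In 15 of the 19 it was replicate 2, in 13 of them as the lowest. Its median log2(CPM + 1) over the tested genes was 0.68, against 4.15 to 4.40. Its list scores were 1.57 for cholesterol efflux (others 4.36 to 4.88), 1.24 for cholesterol synthesis (3.32 to 3.75), 3.44 for T cells (5.94 to 6.37) and 5.13 for B cells (7.35 to 7.50). They were 1.44 for fatty acid oxidation (4.05 to 4.36), 3.72 for the TCA cycle (5.18 to 5.30) and 3.15 for the unfolded protein response (4.13 to 4.32). Abca1 was at 1.23 on the log2 scale (others 6.13 to 6.82), Btla at 6.33 (8.23 to 8.46), Abca7 at 0.20 (4.46 to 5.01), Lpl at 2.20 (4.55 to 4.99) and Prdx1 at 7.0 (7.98 to 8.03). It was the highest for Apoe, at 9.74 (8.05 to 8.10), and for Fcer1g, at 9.83 (8.32 to 8.48).

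Control-LNP replicate 1 was the highest in the other 4. Its list scores were 5.25 for foamy macrophage genes (4.68 to 4.72), 4.41 for contractile smooth muscle genes (3.71 to 3.82) and 9.49 for erythroid markers (6.91 to 7.04), and Hba-a1 was at 12.8 (11.2 to 11.4).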

How the results depend on the processing

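Pseudocounts of 0.25 and 4 CPM, voom, median centring without control-LNP replicate 2 and the 2 added lists were chosen only after the data were seen; the pseudocount of 1 CPM planned as an alternative is the scale of the deposited values and has no value of its own. No gene called in both the reported comparison and another setting changed direction. With any 1 library left out, 1148 of the 1957 genes (58.7%) kept their calls in all 7 fits, 809 of them higher and 339 lower. Leaving out 1 library gave 1372 to 3964 changed genes, 974 to 1982 higher and 398 to 1982 lower, the most without control-LNP replicate 2 and the fewest without control-LNP replicate 4, and 19 to 25 lists. Median centring gave 741 higher and 1249 lower genes, or 4228 changed, 1781 higher and 2447 lower without control-LNP replicate 2, quantile normalization 3015 changed and 1401 lower, and sample weights 4343 changed, 2100 higher and 2243 lower, with a weight of 0.0792 for control-LNP replicate 2 and 7.99 for replicate 4. The remaining settings gave 1683 to 2568 genes, except the 2 that follow. A replicate block gave 1060 changed, 738 higher and 322 lower genes and 20 lists. The deviations of same-numbered libraries from their group means correlated at r = 0.00528, -0.0105 and -0.0173, and 0 of 3 ITA-LNP libraries correlated best with its own number. No pairing by number was seen. This check could miss one, since control-LNP replicate 2 enters the group mean behind every control-LNP deviation and all pairs lay between -0.0322 and 0.0257. The white adipocyte score as a covariate gave 0 changed, 0 higher and 0 lower genes in limma (938 at an unadjusted p under 0.05, smallest adjusted p 0.561) and 12 lists. That score differs between the groups without overlap, so this fit can hardly part the covariate from the group. Calls were lost though some folds stayed large, as for Acta2 (7.08 in place of 6.79) and Gpnmb (9.33 in place of 6.68). Other folds shrank, as for Apoe (0.64 in place of 1.99). Camera with an estimated correlation called 0 lists, where ranks called 22 and fry 25.

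The 20 list scores that passed became 0 with no filter, with a mean of at least 2, with median centring, with quantile normalization and without any 1 library, and 21 with the median of members. An adjusted pass needs at least 20 of the 34 lists at the smallest p, and with 1 library fewer that p is larger. Abcg1 reversed with median centring (-0.30, or -0.35 without control-LNP replicate 2) and quantile normalization (-0.24) and ranged from -0.12 to 1.32 with 1 library left out. Median centring also reversed Psap (-0.13) and Atp5a1 (-0.51). The white adipocyte covariate reversed Abca7 (1.06), Zbp1 (0.31), Ucp1 (-2.92) and Cx3cr1 (0.91), the last chosen after its values were seen. It also reversed the glycolysis list (adjusted p = 0.0241) and the heat shock list (adjusted p = 0.603). The causes of these reversals and of the moved counts were not tested, apart from the 2 residual degrees of freedom under the block, where the reported comparison has 5. Of 1817 comparisons of a named gene with a setting that keeps all libraries, 1537 kept direction and side of the threshold, 235 lost the call and 37 gained it; with 1 library left out, 888 of 987 kept both. Depth limits the genes near 0 reads, such as Acod1, at 0.412 to 0.591 CPM.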

Other observations

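The genes named here were chosen after their values were seen, and no test of an explanation was run on them. The most abundant transcripts differed between the groups. Leaving out mitochondrially encoded genes, in the ITA-LNP libraries Acta2 led at 10802 CPM, and Syn3, a synapsin gene, was among the 12 most abundant genes at 4500.2 against 34.8 CPM in the control-LNP libraries (log2 fold change 7.03 ± 0.35, limma adjusted p = 5.84e-06). In the control-LNP libraries Rps27, a ribosomal protein gene with the near-identical copy Rps27rt, led at 11608 against 1711 CPM. Ctla2a, which encodes a cysteine protease inhibitor, was at 9600.2 CPM in the control-LNP and 202 CPM in the ITA-LNP libraries. Tpt1 was high in both, at 5831 CPM with ITA-LNP and 11202 CPM in the control-LNP libraries.

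The last exon of Timp3 (chromosome 10, 86345705 to 86349506, plus strand) and an exon of Syn3 (chromosome 10, 86347774 to 86351640, minus strand) share 1733 bases in the annotation. Syn3 was at 8.49, 9.28 and 13.1 times the CPM of Timp3 in the 3 ITA-LNP libraries. The sources used here do not say whether the counting used strand, so reads of the 2 genes cannot be assigned to 1 of them, and the rise of Timp3 in the protease list carries the same limit.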
